A study of Leucocroton havanensis and Lasiocroton microphyllus with 3 samples.

How the data were processed

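Leaf RNA of 3 samples was sequenced: in vitro and field L. havanensis, and field L. microphyllus. Per the labels' protocols, field leaves were kept in a stabilising solution, total RNA was extracted with a TRIzol reagent and treated with DNase, and polyA libraries that keep the strand were made with an Illumina kit. Per the series' design text, paired-end reads were sequenced, the reads of the in vitro L. havanensis sample were assembled into a transcriptome, and that transcriptome served as the reference for all samples. The aligner, the counting tool, their settings and the treatment of reads that match several contigs are not given in the sources used here. The deposited values are raw read counts per contig, per the file headers, with no normalization. They are whole numbers whose totals differ between the libraries, and both tables list the same 58990 contigs. The in vitro sample was not analysed here. A genome, contig sequences, contig lengths and gene annotation were not used here, so contigs have no coordinates or gene names, and abundance is not corrected for length.

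Counting reads of both species on contigs of 1 of them can lower the counts of the other species where sequences differ, and transcripts that L. havanensis did not yield in vitro have no contig. Contigs of near-identical copies of a gene can share or split reads.

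Counts were used as deposited. Contigs with at least 20 counts summed over both libraries were tested (50943), and the 8047 others held 0.0579% of the L. havanensis counts and 0.0267% of the L. microphyllus counts. Scaling factors came from edgeR 4.0.16 (TMM, trimming 30% of log ratios and 5% of abundances at each end) in R 4.3.3, and were 1.25 for L. havanensis and 0.80 for L. microphyllus, which differs from total-count scaling by 1.56 times. CPM is the count scaled to a library of 1000000 counts, where the library size is the total times this factor. A single count was worth 0.00849 CPM in L. havanensis and 0.0164 CPM in L. microphyllus. The fold of a contig is the ratio of its scaled counts, with the exact Clopper-Pearson 95% interval of the count in 1 library among the counts of both. With 0 counts in 1 library the fold was computed against 3 counts, the one-sided limit that a count of 0 allows, and is given as at least that value. The exact two-sided interval allows more than 3 counts, so its lower limit is smaller and is given beside it. Log2 ratios and correlations used a pseudocount of 1 count, scaled to library size. With 1 library per group, no test of the species can be made and no dispersion can be estimated, and the planned design held none. Reads are not independent molecules where PCR copied them, so intervals and limits of counts, CPM, folds and shares cover counting error only.

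The rules were fixed before the data were examined: the 4-fold limit on the whole interval, the 4 classes of mean abundance, the alternatives, and the contigs to name. With names, 15 contigs in each direction and the metal transport genes would have been named. Without names, the rule gave the 2 contigs with the highest lower limit of the fold in each direction. Gene lists for metal transport, metal chelation, photosynthesis, stress, defence, cell wall, leaf cell types and other organisms were also fixed, and none could be applied. The alternatives were scaling by total counts, by upper quartile and by DESeq2 1.42.0 median of ratios; a minimum of 1 or 100 summed counts; thinning the deeper library at random to the total of the other; fold limits of 2 and 8; the point estimate in place of the interval; leaving out the 10 most abundant contigs of each library; pseudocounts of 0.5 and 5; and leaving out contigs at 0. Summing contigs of 1 component was planned and not run, since the identifiers show no components. TMM factors from contigs with at least 1000 summed counts, and the numbers past 4-fold without contigs at 0, were added after the data were seen.

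The procedure was tested on simulated data with the real contigs' mean abundances and library totals and 200 changed contigs. Of 50 contigs changed 8-fold, 39 were recovered, as were 50 of 50 changed 16-fold and 50 of 50 changed 32-fold. Of 50 changed 2-fold, 0 passed the limit, as did 0 of 50610 unchanged contigs, and 95.8% of the unchanged contigs' intervals held a fold of 1. The simulation has counting error only and no variation between plants. Apart from the changed contigs, both simulated libraries had the same abundances, with a ratio of TMM factors of 1.00 against 1.56 in the real data. It thus does not test the scaling where many contigs differ, or the use of 1 species' reference for both.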

Results

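Leaf polyA RNA was sequenced from Leucocroton havanensis, a nickel hyperaccumulator shrub of the spurge family (Euphorbiaceae), and from Lasiocroton microphyllus, a related species labelled as a non-accumulator. A nickel hyperaccumulator is a plant that stores nickel in its leaves at levels toxic to most plants. The series holds 3 samples, with 1 leaf library per group. The field leaf of L. havanensis and the field leaf of L. microphyllus were compared here. The third sample, L. havanensis grown in vitro on agar medium with 500 mg/L NiSO4, was not analysed here. Each field library gave a read count for each of 58990 contigs of the L. havanensis transcriptome, which was assembled de novo from the reads of the in vitro sample. The L. havanensis library held 94247756 counts and the L. microphyllus library held 76372207 counts. There were no replicates, so no difference below has a replicate check and no p-value is given. Intervals of counts, CPM, folds and shares are 95% intervals that cover counting error only. Intervals of medians, and of differences between medians, come from the 95% limits of medians over contigs. Site and year of collection differed together with the species.

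The comparison asked which leaf transcripts differ in abundance between a nickel hyperaccumulator and a non-accumulating relative. Among 50943 contigs with at least 20 counts summed over both libraries, 8111 were more than 4-fold higher in L. havanensis (15.9%) and 7166 were more than 4-fold higher in L. microphyllus (14.1%). A contig was counted only where the whole interval of its fold lay beyond 4. By the point estimate alone the numbers were 13534 and 8607. That estimate is the plain ratio, so a tested contig at 0 counts in 1 library passed whatever its other count. Without contigs at 0 in either library, an alternative added after the data were seen, they were 5175 and 6274. That filter depends on the difference itself, since it removes 3874 contigs at 0 in L. microphyllus and 892 at 0 in L. havanensis. The remaining 35666 contigs (70.0%) met neither limit, and they held 84.2% of the L. havanensis counts and 68.8% of the L. microphyllus counts. The contigs higher in L. microphyllus held 30.5% of that library's counts and 4.56% of the L. havanensis counts. The contigs higher in L. havanensis held 11.2% of that library's counts and 0.736% of the L. microphyllus counts. The log2 ratio of L. havanensis over L. microphyllus had a median of 0.30 and an interquartile range from -1.22 to 2.08. Its SD over contigs was 3.04. Counting error alone gave an SD of 0.29 in simulated libraries, whose relative depths followed the TMM-scaled totals and not the count totals. That comparison leaves out variation between plants of 1 species. Across contigs, which are not independent replicates, the log2 CPM values of the libraries had a Pearson r of 0.64 and a Spearman rho of 0.66.

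The share of these contigs that was higher in L. havanensis depended on the scaling of the libraries. TMM averages the middle of the log ratios of all tested contigs with counts in both libraries, which ran from -0.30 to 1.92 with total-count scaling. In the most abundant of 4 classes 39.3% of these contigs lay below that range and 10.0% above it, and in the faintest class 16.2% lay below and 47.8% above. With TMM scaling, 53.1% of the 15277 contigs past the limit were higher in L. havanensis. The share was 70.3% with scaling to total counts (12299 contigs against 5196) and 67.0% with upper-quartile scaling (11277 against 5566). It was 48.9% with DESeq2's median-of-ratios scaling (7393 against 7726), which turned the majority around. Relative to TMM, these 3 scalings shifted the log2 fold of every contig with counts in both libraries by 0.64, 0.50 and -0.14. Log2 ratios with the pseudocount shifted less for faint contigs. With total counts, the median of the faintest class moved from 1.65 to 2.25. Under all 4 scalings, 7393 contigs were more than 4-fold higher in L. havanensis and 5196 were more than 4-fold higher in L. microphyllus. A scaling changes all folds by the same factor. These are thus, by construction, the lowest numbers in each direction, from DESeq2 and from total counts.

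**Figure D1:**
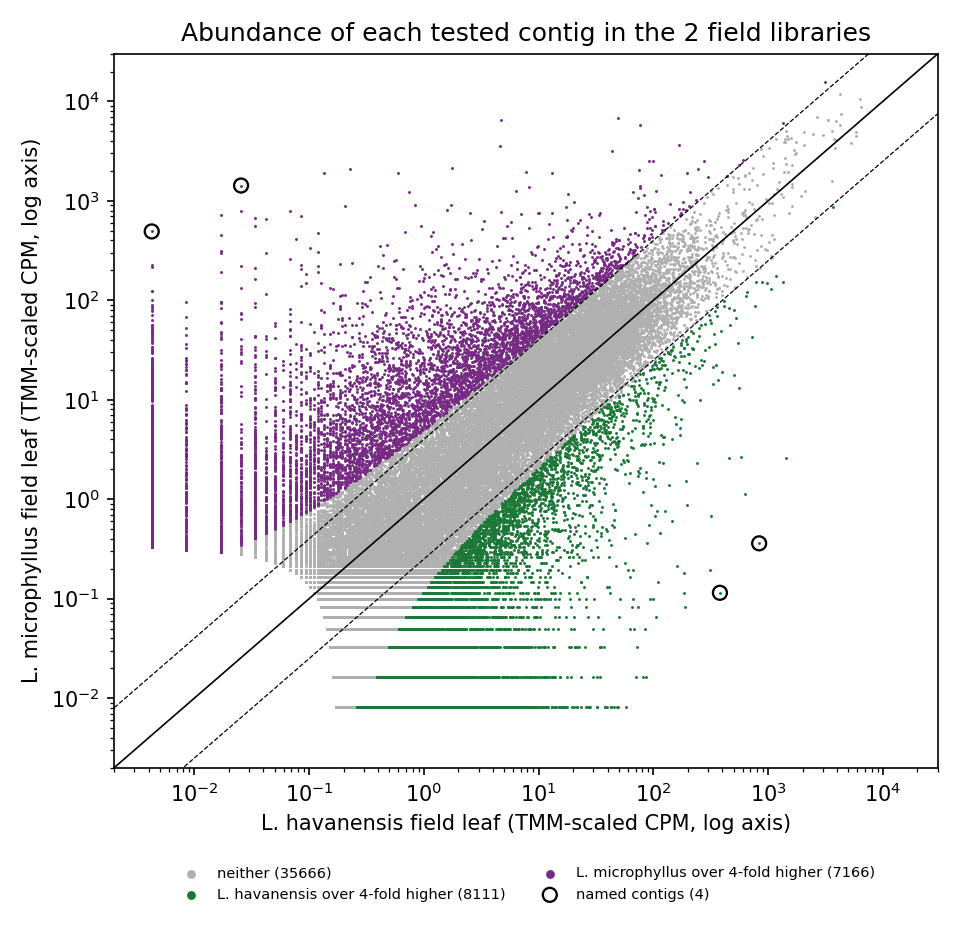
Each point is 1 of 50943 tested contigs, with TMM-scaled CPM in the L. havanensis field leaf on the horizontal axis and in the L. microphyllus field leaf on the vertical axis, both logarithmic; a count of 0 is drawn at the value of 0.5 counts. Green points (8111) and purple points (7166) have fold intervals wholly beyond 4-fold, marked by dashed lines, the solid line marks equal values, and the 4 named contigs are circled.

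The log2 ratio fell with transcript abundance. Contigs were divided into 4 equal classes by their mean TMM-scaled CPM over both libraries, from class 1 (faintest) to class 4 (most abundant). In class 1, 2253 contigs were more than 4-fold higher in L. havanensis and 594 in L. microphyllus. In class 2 the numbers were 3067 and 1757, and in class 3 they were 2150 and 2491. In class 4, with a mean of at least 11.9 CPM, 641 were more than 4-fold higher in L. havanensis and 2324 in L. microphyllus. With total-count scaling the numbers for L. havanensis and L. microphyllus were 4102 and 408 in class 1, 4152 and 1337 in class 2, 2957 and 1882 in class 3, and 1088 and 1569 in class 4. With upper-quartile scaling they were 3676 and 446, 3904 and 1417, 2742 and 2004, and 955 and 1699. The majority in class 3 was thus in L. havanensis under these scalings and in L. microphyllus with TMM, and DESeq2 scaling gave 2000 and 2656 there. TMM factors from contigs with at least 1000 summed counts, chosen after the data were seen, gave 2630 and 2066 in class 3 and a median log2 ratio of -0.12 in class 4. The median log2 ratio was 1.65 (interval 1.60 to 1.72) in class 1, 0.86 (0.79 to 0.91) in class 2, -0.05 (-0.10 to -0.01) in class 3 and -0.55 (-0.58 to -0.51) in class 4. These intervals are exact binomial limits of the median over contigs and do not describe variation between plants. The sign of a class median depended on the scaling, since with total counts class 4 had a median of 0.10 and with upper-quartile scaling class 3 had a median of 0.45. A scaling shifts all contigs nearly alike, and faint ones a little less because of the pseudocount. The classes were kept as set with TMM under every scaling, so the fall from class 1 to class 4 is nearly fixed by construction. Classes set anew under another scaling were not run. The fall was 2.20 over all tested contigs and 1.77 (1.70 to 1.86) over the 46749 contigs above a mean of 0.164 CPM, a level chosen after the data were seen, at which a contig passes the count minimum in either direction. In class 4, 48.3% of contigs lay within 2-fold between the libraries with TMM scaling, against 25.1% in class 1. These shares depend on the scaling and on counting error, which is larger for faint contigs. The fold interval kept out 60.1% of the contigs past 4-fold by the point estimate in class 1 and 5.75% in class 4. In class 1, 2657 contigs had 0 counts in L. microphyllus and 270 had 0 in L. havanensis, and in class 4 the numbers were 15 and 43.

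**Figure D2:**
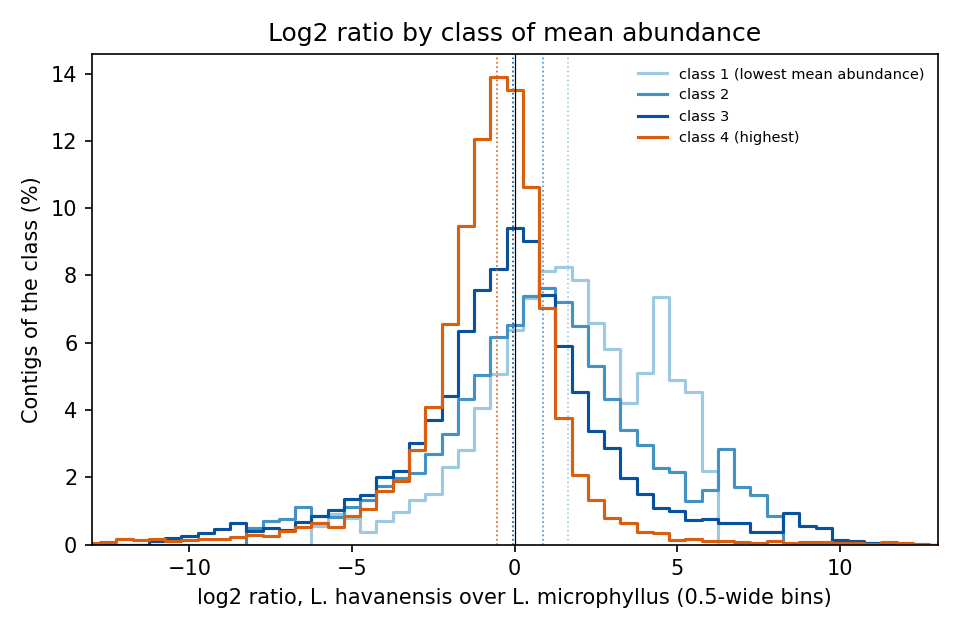
Distribution of the log2 ratio of L. havanensis over L. microphyllus in 4 classes of mean abundance, as the percent of the contigs in each class per bin of 0.5 log2 units; dotted lines mark the class medians. The medians move from 1.65 in class 1 to -0.55 in class 4, and a second peak right of the main one in class 1 lies where contigs with 0 counts in L. microphyllus (2657 in this class) fall.

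Detection differed between the libraries. At least 1 count was present for 56614 contigs (96.0%) in L. havanensis and for 51428 contigs (87.2%) in L. microphyllus. At least 10 counts were present for 50861 (86.2%) and 39253 (66.5%) contigs. Among the tested contigs, 3874 had counts in L. havanensis and 0 in L. microphyllus, and 892 had counts in L. microphyllus and 0 in L. havanensis. Above a mean of 0.164 CPM these numbers were 2489 and 892. A count of 0 allows up to 3 counts, which is 0.0255 CPM in L. havanensis and 0.0491 CPM in L. microphyllus. The contigs seen in L. havanensis alone had a median of 53 counts and together held 0.579% of its counts. Those seen in L. microphyllus alone had a median of 85 counts and held 0.441% of its counts. All contigs were assembled from reads of in vitro L. havanensis. A count of 0 in its field leaf thus does not mean that the species lacks the transcript. With at most 2 counts in the other library, 1805 contigs had at least 100 counts in L. havanensis and 612 had at least 100 counts in L. microphyllus. These limits are unequal in CPM, since 1 count was worth 0.00849 CPM in L. havanensis and 0.0164 CPM in L. microphyllus. An equal CPM was not applied at the minimum of 100 counts. At a minimum of 1000 counts, which is 8.49 CPM in L. havanensis and 16.4 CPM in L. microphyllus, the numbers were 123 and 110. At an equal minimum of 16.4 CPM, set after the data were seen, they were 44 and 110. This minimum is equal on the TMM scale only, and these numbers were not computed with the other scalings. The 110 contigs held 421832 counts of the L. microphyllus library (0.552%), and the 123 contigs held 282001 counts of the L. havanensis library (0.299%).

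The processed files identify contigs by number and do not pair them with gene names, so no transporter, chelator or stress gene could be reported by name. The contigs with the highest lower limit of the fold in each direction are given by their identifiers. Lhav_v1_contig_2732 had 44832 counts in L. havanensis and 7 in L. microphyllus. Its abundance was 381 CPM (377 to 384) against 0.115 CPM (0.0461 to 0.236), a 3322-fold difference (1612 to 8263). Lhav_v1_contig_4141 had 98568 counts in L. havanensis and 22 in L. microphyllus, at 837 CPM (832 to 842) and 0.36 CPM (0.226 to 0.545), a 2324-fold difference (1535 to 3709). For both contigs, the low L. microphyllus counts may reflect reads lost where its sequence differs from the L. havanensis reference. This was not tested, and the intervals do not cover it. In the other direction, Lhav_v1_contig_131 had 87249 counts in L. microphyllus and 3 in L. havanensis, at 1428 CPM (1418 to 1437) and 0.0255 CPM (0.00525 to 0.0744), and the ratio was 56068 (19185 to 271886). Lhav_v1_contig_17684 had 30130 counts in L. microphyllus and 0 in L. havanensis. It was at 493 CPM (488 to 499) in L. microphyllus and at least 19362-fold higher there against the 3 counts that a count of 0 allows. The lower limit of its exact two-sided interval, the limit used to rank contigs, was 15746-fold. The log2 of its fold was 14.2 with TMM, 13.6 with total-count, 13.7 with upper-quartile and 14.4 with DESeq2 scaling. With total counts and upper quartile the fold lay below that lower limit. The CPM values, folds and limits given here thus hold for TMM scaling only. Under the other scalings, the folds of the other named contigs stayed within their intervals. Lhav_v1_contig_131 and Lhav_v1_contig_17684 were, like all contigs, assembled from reads of in vitro L. havanensis. Their near-absence from its field leaf thus does not mean that the species lacks them. Intervals of CPM are exact Poisson intervals.

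The most abundant transcripts were partly shared. The 100 most abundant contigs held 22.5% of the L. havanensis counts and 26.2% of the L. microphyllus counts. The exact binomial intervals were 22.51% to 22.52% and 26.15% to 26.17%. Of these, 55 contigs were in both lists, where independent lists from the tested contigs would share 0.196. Both are leaf libraries counted on the same contigs without correction for length, so far more sharing than that was likely beforehand. The contrast does not measure how alike the species are. Among the 100 most abundant contigs of L. havanensis, 11 were more than 4-fold higher in that species, 2 were more than 4-fold higher in L. microphyllus, and 52 lay within 2-fold. Among the 100 most abundant contigs of L. microphyllus, 34 were more than 4-fold higher in that species, 0 were more than 4-fold higher in L. havanensis, and 33 lay within 2-fold. Each list was picked by counts in its own library, which favours that direction. These numbers used TMM scaling only. In class 4 as a whole, calls for L. havanensis and L. microphyllus were 641 and 2324 with TMM and 1088 and 1569 with total counts. The most abundant contig took 0.808% of the counts in L. havanensis and 1.27% in L. microphyllus. The 1000 most abundant contigs held 47.2% of the counts in L. havanensis and 51.1% in L. microphyllus.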

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

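With 1 library per group, no replicate could be left out and no blocked fit was possible, and neither biological nor technical spread can be estimated. Counting error kept out 60.1% of the contigs past 4-fold by the point estimate in class 1, 26.7% in class 2, 12.2% in class 3 and 5.75% in class 4. The point estimate passed every tested contig at 0 in 1 library and did not use the limit of 3 counts. The number of contigs more than 4-fold higher in L. havanensis was 12299 with total-count scaling, 13534 by the point estimate, and 5175 (against 6274 for L. microphyllus) without contigs at 0, an alternative chosen after seeing the data, which leaves out contigs that had passed the limit. With limits of 2-fold and 8-fold the numbers were 14791 and 4032 for L. havanensis and 12224 and 4374 for L. microphyllus, so the 8-fold limit turned the majority to L. microphyllus. The other alternatives stayed within 1.5 times the main counts, although upper-quartile scaling gave 11277 and 5566. TMM factors from contigs with at least 1000 summed counts, chosen after seeing the data, gave 10740 and 5775. The median log2 ratio stayed above 0 under every alternative run. It was 0.93 with total-count, 0.16 with DESeq2 and 0.80 with upper-quartile scaling, 0.72 with the factors of contigs over 1000 counts, 0.40 with no filter, 0.12 with at least 100 counts, 0.26 with the deeper library thinned, and 0.13 without contigs at 0. Contigs seen in L. havanensis alone numbered 6859 with no filter, 1090 with at least 100 counts and 6645 where up to 2 counts passed as absent. The numbers for L. microphyllus alone were 1673, 416 and 1356. Spearman's rho was 0.69 with no filter, 0.62 with at least 100 counts and 0.70 without contigs at 0. Pearson's r was 0.70, 0.51 and 0.71 in these cases, 0.63 with the deeper library thinned, and 0.70 and 0.61 with pseudocounts of 5 and 0.5. The 10 most abundant contigs held 6.31% of the L. havanensis counts and 7.02% of the L. microphyllus counts, and the 1000 most abundant held 47.2% and 51.1%. Where the cause of a change is not stated, the cause was not tested. Gene lists and sums over components were not run, because the contigs carry no names or components.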

Other observations

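The test of contigs at 0 in the library thinned to equal totals and the reading of the reference transcriptome were chosen only after their results were seen. The other tests were set before their own results were seen, after the patterns they bear on. Contig numbers were related to abundance in these libraries: across the 50943 tested contigs, contig number and mean CPM had a Spearman rho of -0.75, with contigs not being independent replicates.

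The median log2 ratio of L. havanensis over L. microphyllus was 2.20 higher in the class of faintest contigs than in the class of most abundant ones (interval 2.12 to 2.29). This interval takes the outer limits of the class medians over contigs and does not describe variation between plants. The tables argue against depth as the whole cause: with the L. havanensis library thinned to the other's total, the difference was 2.07 to 2.11 over 20 draws, and it was 1.75 to 1.78 when thinned until 1 count was worth the same TMM-scaled CPM in both. The minimum of 20 summed counts admits fainter contigs of the deeper library, and among the 46749 contigs above a mean of 0.164 CPM, where either direction passes the minimum, the difference was 1.77 (1.70 to 1.86), so depth and the minimum may account for a part of it and not for the whole. A reference assembled from L. havanensis, through lost reads or the choice of contigs, could give a difference above 0, for example if stronger for faint contigs. Whether it was stronger there was not tested. An effect by the same factor on every contig would shift the class medians nearly alike. An effect on only some contigs could give a difference at any abundance, since the classes use the mean of both libraries. As a source of the 2.20 seen, the reference cannot be told apart from the species, the sites or the years. Contig sequences were not used here and each group has 1 library.

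Among the tested contigs, those at 0 counts were 4.34 times as many in L. microphyllus (3874) as in L. havanensis (892), and over all 58990 contigs the numbers at 0 were 7562 and 2376. The tables argue against depth as the whole cause: after thinning to equal totals, which left the L. havanensis library 1.56 times deeper on the TMM scale, the ratio was 3.64 to 3.74 over 20 draws, and after thinning to equal depth on that scale it was 2.30 to 2.43. Above a mean of 0.164 CPM, 2489 contigs were at 0 in L. microphyllus and 892 in L. havanensis, a ratio of 2.79, so depth and the minimum count may explain a part of it. Sequence differences from the reference, the choice of contigs and a difference between the species stay open and were not tested on this pattern.

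More contigs were past the 4-fold limit in L. havanensis than in L. microphyllus by a ratio of 1.13 with TMM scaling. Tests set after this majority was seen, and before their own results, asked whether removing a depth gap or a few abundant contigs brings this ratio close to 1. The ratio already met the bound set for them, so they decide nothing: it was 1.15 at the lowest over the 20 thinned draws and 1.13 without the 10 most abundant contigs of each library. Over the 4 scalings the ratio ran from 0.957 with DESeq2 to 2.37 with total counts, and with TMM it was 0.922 at the 8-fold limit, which suggests that the overall balance between the species cannot be read from these libraries.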
